A study of Homo sapiens with 4 samples.

How the data were processed

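RNA of HepG2 cells treated for 48 h with DMSO or AMF was sequenced after poly(A) selection with a kit that does not keep strand, per the labels' protocols. STAR 2.7.0, featureCounts and the genome build hg19 are named in the submitters' processing notes. The gene annotation, read filters and normalization are not given in the sources used here. The deposited table held log2-scale values for 30863 genes in 4 libraries, 2 of DMSO and 2 of AMF, with gene symbols as identifiers and every gene seen in at least 1 read. Its columns were matched to samples by name, and 0 columns of other samples were present. The values were bounded below by 6.01 in each library and had the form of a variance-stabilizing transformation of counts divided by a size factor per library, which is read from the values and not stated by the labels. With f as that lowest value and V as a deposited value, the normalized count is 2^V - 2·2^f + 2^(2f - V).

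The smallest positive normalized count of a library was taken as the worth of 1 read, refined over genes of low count. Divided by it, 100% of the values in each library were whole within 0.01 reads. The same steps on simulated counts returned 100% of them. Size factors came to 1.0004 and 0.974 for DMSO replicates 1 and 2 and to 1.0769 and 0.9707 for AMF replicates 1 and 2, and equalled median-of-ratios factors computed from the recovered reads to 4 decimals. Totals per library ranged from 24226586 to 26966210 reads. A single read equals 0.929 to 1.03 normalized counts, and a floor of 3 reads equals 2.79 to 3.09 per library. Floors and read-ratio intervals (95%, exact binomial on reads, conditional on their sum) cover counting error only, since reads without molecular identifiers are not independent molecules.

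Tests were run with limma 3.58.1 in R 4.3.3. The design fixed before the data were examined foresaw counts, normalized values or a table of comparisons. Since the deposited unit was log2, no count model was used, and the test planned for normalized values was taken. This was limma-trend on log2(normalized count + 1) for the 23828 genes with a mean of at least 1 normalized count, with the group as the sole term and Benjamini-Hochberg adjustment. Fold changes on this scale understate the change of genes with low counts. Gene lists (42, fixed before the data were examined) were tested with camera at a preset correlation of 0.01 and with an estimated correlation, with adjustment over the 41 lists that had at least 5 tested members. With an estimated correlation 0 lists passed, with 3 at an unadjusted p under 0.05, whereas with the preset correlation 23 passed and with fry 22. The calls that ended include lists whose estimated correlation lay below 0.01. Camera with an estimated correlation refers each list to the residual degrees of freedom, which are few with 4 libraries in 2 groups. The end of a call at that setting therefore says little of the list itself. List members without a row in the deposited table were not analysed here.

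Named genes followed a rule fixed before the data were examined. ULK1, MAP1LC3B and SQSTM1 were always named. The 8 largest rises and 8 largest falls, and the 4 rising and 4 falling genes with the smallest p, were taken among genes past the threshold with a known symbol, a mean of at least 100 normalized counts and both AMF libraries on the same side of both DMSO libraries. From each list came up to 4 members, the 2 largest rises and 2 largest falls past the threshold with a mean of at least 10. Gene names, types, lengths and exon overlaps came from GENCODE release 29 and RefSeq tables on another build than hg19, so no coordinates are given. Exons of 63 of the 166 named genes overlapped those of another gene there. Of the table's symbols, 21620 matched a GENCODE name and 15837 of those were protein coding. Without strand, reads of a gene and of an antisense or overlapping neighbour cannot be told apart.

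The tests were tried on simulated counts with the real levels and size factors, in which 200 genes were changed. All genes had the same dispersion of 0.0025, taken from genes with a mean of at least 100. The changed genes were drawn from those with a mean of at least 10, so the recovery does not cover genes of lower mean. Over 22729 genes simulated for AMF against DMSO, limma-trend recovered 70.1% of genes changed 1.5-fold, 89.6% of those changed 2-fold and 97.0% of those changed 4-fold, with 1 false call, and voom recovered 73.1%, 89.6% and 97.0% with 4 false calls. Alternatives planned beforehand were a pseudocount of 0.1, no filter, each library left out, the replicate number as a block, stricter thresholds, named genes alone, and for lists ranks, higher levels, fry and the block. Added after seeing the data were the deposited log2 values, voom on the recovered reads with and without each library, library totals as scaling, a mean of at least 10, and lists without each library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.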

Results

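The series holds poly(A)-selected RNA sequencing of HepG2, an established human liver cancer cell line that the labels call hepatoblastoma. Cells received the solvent DMSO or amentoflavone (AMF), a plant biflavonoid, for 48 h. Each group has 2 libraries, numbered as replicates 1 and 2. The labels disagree on the treatment, since the protocol gives 90 µM AMF whereas the design text names 80 µM of an agent called Tub B, so the compound and the dose are uncertain and AMF stands here for the group that the sample names call so. Reads counted in genes came to 25532946 and 24591071 in DMSO replicates 1 and 2 and to 26966210 and 24226586 in AMF replicates 1 and 2. Reads were found for 23929 and 24108 genes in the DMSO libraries and for 25985 and 25632 genes in the AMF libraries. Mitochondrially encoded genes took 7.73% and 7.69% of the reads in DMSO and 9.53% and 9.61% in AMF. Read counts of the DMSO pair differed by more than counting noise (chi-square per degree of freedom 4.33), as did those of the AMF pair (2.37). Pairs across the groups gave 70.2 to 71.8. Nothing in the labels says that the replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical. Values below are normalized counts as mean ± SD (n = 2 per group), changes are log2 fold changes of AMF against DMSO on the log2(normalized count + 1) scale, and p-values are from limma.

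The comparison of AMF with DMSO asks which transcripts differed after 48 h, in a study whose title concerns autophagy and ULK1 phosphorylation. The aryl hydrocarbon receptor target genes CYP1A1 and CYP1A2, cytochrome P450 enzymes that oxidise aromatic compounds, were among the genes that rose by most. CYP1A1 went from 196 ± 15.2 in DMSO to 43521 ± 939.9 in AMF, a log2 change of 7.79, SE 0.0574, with adjusted p = 9.44e-19. CYP1A2 had 6.65 ± 6.57 in DMSO and 10111 ± 374 in AMF, a log2 change of 10.70, SE 0.402, with adjusted p = 1.43e-10. The aldehyde dehydrogenase ALDH3A1 rose by 6.14, the ATPase-interacting protein NKAIN1 by 7.16, the gel-forming mucin MUC5AC by 5.65, the water channel AQP3 by 5.53 and the hair keratin KRT37 by 5.50. The lens membrane protein LIM2 had 1 read over both DMSO libraries and 495 over both AMF libraries, a ratio of 477, 95% exact interval 85.3 to 18889.6. Among genes with a mean of at least 100 normalized counts, the largest falls were those of the histidine ammonia-lyase HAL (-4.98, from 223 ± 27.3 in DMSO to 7.12 ± 5.69 in AMF), the focal adhesion protein TNS1 (-4.40) and the carbonic anhydrase CA9 (-3.59). The amino acid transporter SLC6A14 (-2.77), the sulfotransferase CHST15 (-2.74), the transcription factor MYCN (-2.64), the acyl-CoA synthetase ACSM3 (-2.51) and the neurotrophin receptor NGFR (-2.28) followed. The change of CYP1A2 was 9.68 and 11.72 without DMSO replicates 1 and 2, and that of HAL -5.77 and -4.20 without AMF replicates 1 and 2. By smallest p, the Ras exchange factor SOS1 (2.38, SE 0.0433, adjusted p = 8.62e-14) and the monocarboxylate transporter SLC16A6 (3.94, SE 0.0729, adjusted p = 8.62e-14) joined CYP1A1 and ALDH3A1 among the rises. The growth factor IGF2 (-2.24, SE 0.0566), the secreted glycoprotein AHSG (-1.39, SE 0.036), the R-spondin receptor LGR5 (-1.91, SE 0.0506) and CHST15 had the smallest p among the falls, with an adjusted p from 3.28e-12 for IGF2 to 6.42e-12 for CHST15. CYP1A1 and CYP1A2 are close paralogs, and exons of ALDH3A1, KRT37, TNS1, CA9, MYCN, ACSM3, NGFR, SLC16A6, IGF2 and LGR5 overlap those of other genes, so their reads may include some of a neighbour in these libraries without strand.

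Of 23828 genes tested, 7578 passed an adjusted p of 0.05, of which 3718 were higher and 3860 lower in AMF. With a log2 change of at least 1 in addition, 1672 genes passed, 1183 higher and 489 lower. With limma-trend, 3531 genes passed without DMSO replicate 1 and 3442 without DMSO replicate 2, but 0 passed without AMF replicate 1 or without AMF replicate 2, when 6575 and 6387 genes had an unadjusted p under 0.05. A fit with voom on the recovered reads called 7714 genes with all libraries, 6776 and 6580 without DMSO replicates 1 and 2, and 1379 and 1315 without AMF replicates 1 and 2. The prior degrees of freedom of limma-trend fell from 11.9 to 0.995 and 1 without AMF replicates 1 and 2, so the 0 calls there say nothing of single genes. Of 166 genes named by the rule, 119 and 121 passed with limma-trend without DMSO replicates 1 and 2, 75 also passed with voom without AMF replicate 1, and 75 without AMF replicate 2. In all 166 both AMF libraries lay on the same side of both DMSO libraries, so leaving out 1 library could not reverse their direction. Their fold changed by less than 1.5 times for 165 without AMF replicate 1 or 2 and for 163 without DMSO replicate 1 or 2. The others were HAL, and CYP1A2, OAS2 and VWF, whose values are given with them.

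**Figure D1:**
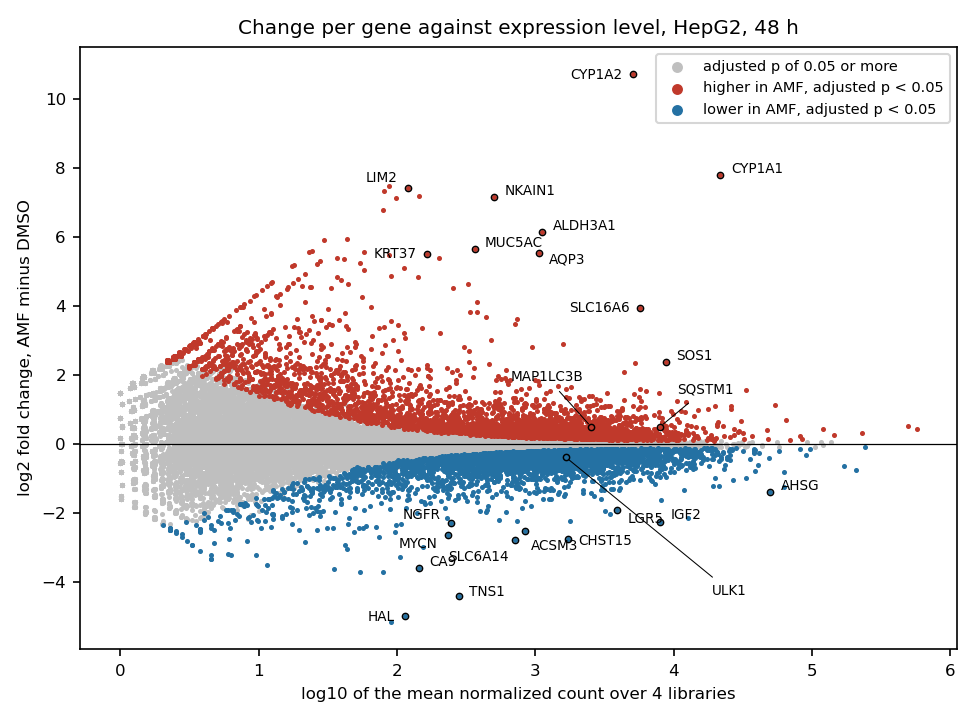
Log2 change of AMF against DMSO for each tested gene (vertical axis) against the log10 of its mean normalized count over the 4 libraries (horizontal axis), with red and blue for the genes higher and lower at an adjusted p under 0.05 and grey for the rest. Circles mark the genes that were always named or named for the largest changes or the smallest p, not those named from lists alone. Among the circled genes CYP1A2 at 10.70 and CYP1A1 at 7.79 lie highest and HAL at -4.98 lies lowest.

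The transcript of ULK1, the kinase that starts autophagosome formation, fell, with 1894 ± 93.8 in DMSO and 1451 ± 33.1 in AMF, a log2 change of -0.38, SE 0.0596, and an adjusted p of 1.56e-04. Phosphorylation of ULK1 is not seen in RNA. MAP1LC3B, which encodes the autophagosome membrane protein LC3B, rose from 2109.9 ± 205 in DMSO to 2979 ± 142 in AMF (0.50, SE 0.0652, adjusted p = 3.17e-05). The cargo receptor SQSTM1 (p62) rose from 6616 ± 328 in DMSO to 9405 ± 178 in AMF (0.51, SE 0.0448, adjusted p = 7.08e-07). Of 44 genes of the autophagy machinery, 15 rose, 6 fell and 23 did not pass (16 up and 6 down adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.126; adjusted p = 0.527 with an estimated correlation). Fry called that list higher (adjusted p = 0.043). Its largest rises were in ATG9B, a member of the ATG9 scramblase family (1.36), and the LC3 protease ATG4A (0.81), and its largest falls in ULK1 and ATG14 (-0.34), a subunit of the class III lipid kinase complex. Of 44 lysosomal genes, 16 rose, 9 fell and 19 did not pass (18 up and 9 down adjusted over the list alone), and the list was higher in AMF (camera adjusted p = 0.0274; adjusted p = 0.446 with an estimated correlation). The cathepsin CTSZ (1.32) and the acid lipase LIPA (1.002) rose, whereas TFEB (-0.87), a transcription factor for lysosomal genes, and the glucuronidase GUSB (-0.50) fell. Of 29 subunits and regulators of AMPK and mTORC1, 4 rose, 12 fell and 13 did not pass (5 up and 12 down adjusted over the list alone), and the list was lower in AMF (camera adjusted p = 0.0307; adjusted p = 0.446 with an estimated correlation). The mTOR inhibitor DEPTOR (-1.16) and SESN3 (-0.94), a sestrin, fell, and the mTORC1 substrate AKT1S1 (0.32) and the mTORC1 activator RHEB (0.26) rose. Without AMF replicate 1 or 2 the call ended for the lysosomal list (adjusted p = 0.102 and 0.0953) and for the AMPK and mTORC1 list (0.0826 and 0.0734). The AMPK and mTORC1 call also ended among genes with a mean of at least 100 (adjusted p = 0.32) and with the replicate number as a block (0.0676). Exons of ATG9B, MAP1LC3B, SQSTM1, LIPA, DEPTOR, SESN3 and AKT1S1 overlap those of neighbouring genes.

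Genes of foreign-compound metabolism and of the oxidative stress response were higher in AMF. Of 11 tested genes on the aryl hydrocarbon receptor list, 8 rose, 1 fell and 2 did not pass (9 up and 1 down adjusted over the list alone), led by CYP1A2 and CYP1A1 (camera adjusted p = 8.77e-07; adjusted p = 0.446 with an estimated correlation). The fall was that of NFE2L2 (-0.29, adjusted p = 9.74e-05), which encodes the transcription factor NRF2 and stands on that list as well as on the NRF2 list. Of 19 genes of drug metabolism, 13 rose, 0 fell and 6 did not pass (14 up and 0 down adjusted over the list alone; camera adjusted p = 5.74e-08, adjusted p = 0.446 with an estimated correlation). The bilirubin glucuronosyltransferase UGT1A1 rose from 116 ± 7.83 in DMSO to 1317 ± 28.2 in AMF (3.49, SE 0.095, adjusted p = 5.47e-12), and the glutathione transferase GSTA2 rose by 1.66. Of 27 NRF2 targets and glutathione genes, 23 rose, 3 fell and 1 did not pass (23 up and 4 down adjusted over the list alone), and the list was higher (camera adjusted p = 9.43e-13; adjusted p = 0.446 with an estimated correlation). The aldo-keto reductase AKR1C1 rose from 16682 ± 1553 in DMSO to 49877 ± 2676 in AMF (1.58, SE 0.0536) and GCLM, a subunit of the enzyme that limits glutathione synthesis, rose by 1.39, whereas the glutathione peroxidase GPX2 fell by 0.93. Of 9 metallothionein and zinc export genes, 5 rose, 1 fell and 3 did not pass (5 up and 1 down adjusted over the list alone), and the list was higher (camera adjusted p = 0.0185; adjusted p = 0.446 with an estimated correlation). MT2A (1.59) and MT1A (1.44) rose, and the metal exporter SLC30A10 (-1.15) fell. The metallothionein median was 0.19 higher (log2) in DMSO replicate 1 than in DMSO replicate 2, and its call ended without AMF replicate 1, AMF replicate 2 or DMSO replicate 2 (adjusted p = 0.209, 0.0734 and 0.107). The UGT1A genes share exons, and the AKR1C, GSTA and MT1 genes have close paralogs, so the split of reads among the members of each family is uncertain.

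**Figure D2:**
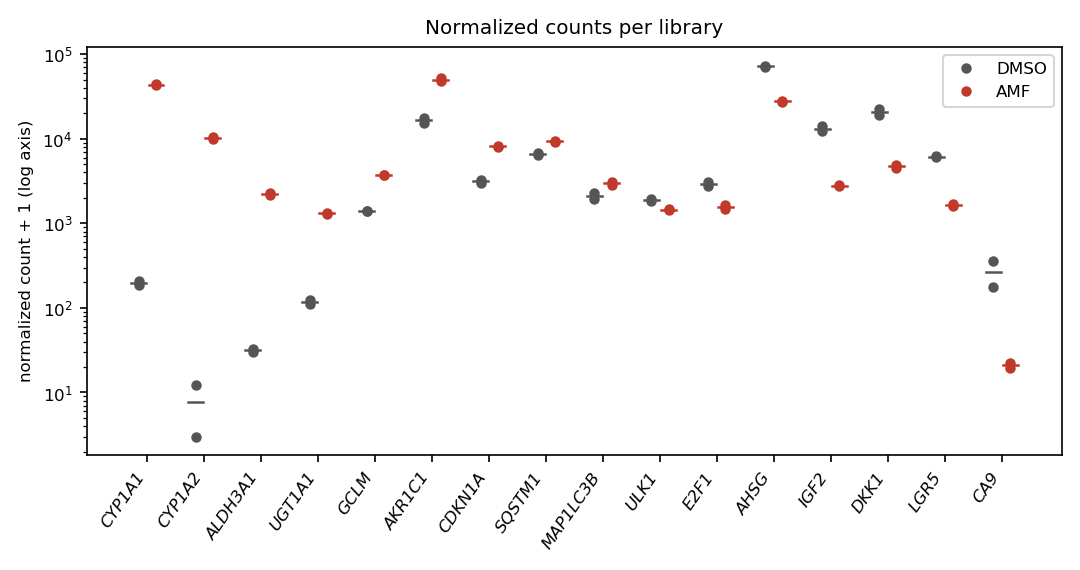
Normalized count + 1 (logarithmic vertical axis) of 16 named genes in each library, with grey points for the 2 DMSO and red points for the 2 AMF libraries and a horizontal line at each group's mean. CYP1A1, at 196 in DMSO and 43521 in AMF, shows one of the widest gaps, and the DMSO libraries of CA9 lie apart from each other.

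Cell cycle genes were lower in AMF. Of 40 genes of S phase and DNA replication, 1 rose, 32 fell and 7 did not pass (1 up and 34 down adjusted over the list alone). The S phase list was lower (camera adjusted p = 9.43e-13; adjusted p = 0.446 with an estimated correlation). Falls were largest in the transcription factor E2F1, with 2947 ± 235 in DMSO and 1582 ± 123 in AMF (-0.90, SE 0.0675, adjusted p = 1.39e-07), and in RRM2, a ribonucleotide reductase subunit (-0.77). The member that rose was the cyclin CCNE1 (0.28, adjusted p = 0.0107). Of 38 genes of G2 and mitosis, 0 rose, 28 fell and 10 did not pass (0 up and 29 down adjusted over the list alone). The mitosis list was lower (camera adjusted p = 1.30e-11; adjusted p = 0.446 with an estimated correlation). The topoisomerase TOP2A (-0.67, SE 0.0415) and the spindle motor KIF11 (-0.66) fell. The S phase and mitosis medians were 0.14 and 0.10 higher (log2) in DMSO replicate 1 than in DMSO replicate 2. Of 23 p53 target genes, 11 rose, 4 fell and 8 did not pass (11 up and 4 down adjusted over the list alone). The p53 list was higher (camera adjusted p = 0.0267; adjusted p = 0.446 with an estimated correlation). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose from 3127 ± 133 in DMSO to 8130.5 ± 99.8 in AMF (1.38, SE 0.0463, adjusted p = 4.39e-11), TP53I3 rose by 0.65, and the BH3-only gene PMAIP1 (-0.60) and the cyclin CCNG1 (-0.52) fell. Of 26 genes of the BCL2 family, caspases and their inhibitors, 9 rose, 10 fell and 7 did not pass (9 up and 10 down adjusted over the list alone), and the list did not pass (camera adjusted p = 0.932; adjusted p = 0.947 with an estimated correlation), with a median log2 change of -0.02 and a mean of 0.02. The initiator caspase CASP8 (0.69) and the BH3-only gene BIK (0.62) rose, and BCL2 (-0.62) fell. The p53 call ended without AMF replicate 1, AMF replicate 2 or DMSO replicate 2 (adjusted p = 0.249, 0.105 and 0.123).

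Among stress responses, heat shock genes were higher and targets of ATF4 lower. Of 14 cytosolic heat shock genes, 11 rose, 1 fell and 2 did not pass (11 up and 1 down adjusted over the list alone). The heat shock list was higher (camera adjusted p = 1.15e-07; adjusted p = 0.446 with an estimated correlation). The inducible HSP70 gene HSPA6 had 0 reads in both DMSO libraries and 161 ± 21.5 normalized counts in AMF, at least 105-fold higher against a floor of 3 reads over the DMSO group. HSPA1A rose from 872 ± 158 in DMSO to 2730.1 ± 58.0 in AMF (1.66, SE 0.091), with reads shared with its near-identical copy, and the small heat shock gene HSPB1 fell (-0.18, adjusted p = 0.00545). Of 30 genes of the integrated stress response, 6 rose, 19 fell and 5 did not pass (7 up and 20 down adjusted over the list alone). The stress response list was lower (camera adjusted p = 1.15e-04; adjusted p = 0.609 with an estimated correlation). The transcriptional repressor JDP2 (-1.64) and the mTORC1 inhibitor DDIT4 (-0.83) fell, whereas the secreted stress factor GDF15 (0.66) and the chromatin protein NUPR1 (0.65) rose. Of 20 genes of the endoplasmic reticulum chaperones and unfolded protein response, 9 rose, 3 fell and 8 did not pass (9 up and 3 down adjusted over the list alone), and the list did not pass (camera adjusted p = 0.054; adjusted p = 0.613 with an estimated correlation). MANF (0.75) and SDF2L1 (0.71), both made in the endoplasmic reticulum, rose, and the transcription factor XBP1 (-0.70) and the chaperone CALR (-0.19) fell. Between DMSO replicates 1 and 2 the list medians differed by 0.17 for heat shock, 0.14 for the chaperones and -0.25 for the integrated stress response (log2, replicate 1 minus replicate 2). The integrated stress median changed by -0.355 in AMF, and by -0.26 and -0.43 against DMSO replicates 1 and 2 alone. Its change against DMSO replicate 1 was thus close in size to the gap between the DMSO libraries. Fry did not call that list (adjusted p = 0.123). The chaperone list passed without DMSO replicate 1 (adjusted p = 0.014) and with library totals as scaling (0.0279).

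Genes of lipid synthesis were higher and hypoxia-responsive and glycolytic genes lower in AMF. Of 21 genes of fatty acid and triglyceride synthesis, 14 rose, 3 fell and 4 did not pass (17 up and 3 down adjusted over the list alone). The lipid synthesis list was higher (camera adjusted p = 8.77e-07; adjusted p = 0.446 with an estimated correlation). The fatty acid synthase FASN rose from 33785 ± 5172 in DMSO to 73770.2 ± 900.1 in AMF (1.14, SE 0.0678, adjusted p = 1.38e-08) and the acyltransferase GPAM by 0.93, while the acyltransferase DGAT2 (-0.48) and the carboxylase ACACB (-0.41) fell. Of 23 genes of cholesterol synthesis and uptake, 15 rose, 1 fell and 7 did not pass (17 up and 2 down adjusted over the list alone). The cholesterol list was higher (camera adjusted p = 5.52e-06; adjusted p = 0.564 with an estimated correlation). The sterol oxidase MSMO1 (1.13) and the synthase HMGCS1 (0.89) rose. Of 23 genes of fatty acid oxidation and ketone body formation, 11 rose, 4 fell and 8 did not pass (11 up and 4 down adjusted over the list alone). The fatty acid oxidation list was higher (camera adjusted p = 0.00344; adjusted p = 0.446 with an estimated correlation). The carnitine carrier SLC25A20 (0.90) and the carnitine transferase CPT1A (0.79) rose, and ANGPTL4 (-1.18) and the ketone body enzyme BDH1 (-0.64) fell. Of 35 hypoxia targets and glycolytic genes, 2 rose, 25 fell and 8 did not pass (2 up and 25 down adjusted over the list alone). The hypoxia and glycolysis list was lower (camera adjusted p = 9.59e-10; adjusted p = 0.446 with an estimated correlation). CA9 fell from 268 ± 132 in DMSO to 19.9 ± 1.99 in AMF (-3.59, SE 0.284, adjusted p = 2.31e-07) and the prolyl hydroxylase EGLN3 by 2.91. The phosphofructokinase PFKP rose (1.16), as did the carbonic anhydrase CA12, with 1 read over the DMSO libraries and 78 over the AMF libraries (ratio 75.2, 95% exact interval 13.1 to 3008). In DMSO replicate 1 the cholesterol median lay 0.33 and the hypoxia median 0.19 (log2) above DMSO replicate 2. The fatty acid oxidation call ended without AMF replicate 1 (adjusted p = 0.0529).

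Transcripts of liver-secreted proteins were mostly lower in AMF. Of 31 hepatocyte products and identity factors, 6 rose, 18 fell and 7 did not pass (6 up and 19 down adjusted over the list alone). The hepatocyte list was lower (camera adjusted p = 3.78e-04; adjusted p = 0.527 with an estimated correlation). AHSG fell from 72474 ± 1475 in DMSO to 27644 ± 935 in AMF and the iron carrier TF by 0.97 (log2), whereas the nuclear receptor HNF4A, with 7049 ± 6.24 in DMSO and 12820.1 ± 355 in AMF (0.86, SE 0.0401), and the tyrosine aminotransferase TAT (0.98) rose. Of 19 acute phase and complement genes, 1 rose, 12 fell and 6 did not pass (1 up and 13 down adjusted over the list alone). The acute phase list was lower (camera adjusted p = 8.77e-07; adjusted p = 0.446 with an estimated correlation). Complement C5 fell from 5026 ± 207 in DMSO to 1322 ± 116 in AMF (-1.93, SE 0.0624, adjusted p = 2.81e-11) and the inter-alpha-trypsin inhibitor chain ITIH3 by 1.58, and the interleukin 6 receptor IL6R rose (0.67). Of 15 bile acid genes, 2 rose, 4 fell and 9 did not pass. The bile acid list did not pass (camera adjusted p = 0.3; adjusted p = 0.609 with an estimated correlation). The phospholipid exporter ABCB4 (-1.13) and the bile acid receptor NR1H4 (-1.03) fell. BAAT (1.23) and SLC27A5 (0.52), which conjugate or activate bile acids, rose. Of 17 genes of the urea cycle and amino acid breakdown, 7 rose, 2 fell and 8 did not pass. The amino acid list did not pass (camera adjusted p = 0.0505; adjusted p = 0.446 with an estimated correlation). SDSL (1.35) and the tyrosine pathway enzyme FAH (1.13) rose, and OAT (-0.27) and CPS1 (-0.24) fell. With library totals as scaling the amino acid list was higher (adjusted p = 0.0364), as it was with fry (0.043) and the replicate block (0.0136). Of 13 genes of gluconeogenesis, glycogen and FOXO targets, 3 rose, 5 fell and 5 did not pass. The glucose transporter SLC2A2 (1.12) and the carboxylase PC (0.69) rose, and IRS2 (-1.12) and TXNIP (-0.97) fell. That list did not pass (camera adjusted p = 0.387; adjusted p = 0.575 with an estimated correlation), and its test pointed down against a median log2 change of 0.01 and a mean of 0.06. Of 19 genes of iron handling and ferroptosis, 6 rose, 7 fell and 6 did not pass. The iron list did not pass (camera adjusted p = 0.51; adjusted p = 0.831 with an estimated correlation). The heme oxygenase HMOX1 (1.31) and LPCAT3 (0.49) rose, and TF and the iron importer SLC11A2 (-0.73) fell. Adjusted over each list alone, 2 bile acid genes rose and 5 fell, 9 and 2 amino acid genes, 3 and 6 gluconeogenesis genes, and 7 and 8 iron genes.

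Targets of the Wnt and Hippo pathways were lower on balance. Of 16 beta-catenin targets, 3 rose, 9 fell and 4 did not pass (4 up and 9 down adjusted over the list alone). The beta-catenin list was lower (camera adjusted p = 0.00541; adjusted p = 0.446 with an estimated correlation). The secreted Wnt inhibitor DKK1 fell from 20663 ± 2509 in DMSO to 4733 ± 319 in AMF (-2.12, SE 0.0661, adjusted p = 1.97e-11) and LGR5 from 6159 ± 175 in DMSO to 1643 ± 60.5 in AMF, while the transcription factor TBX3 (0.87) and the growth factor BMP4 (0.82) rose. Of 14 YAP and TEAD targets, 4 rose, 7 fell and 3 did not pass (4 up and 7 down adjusted over the list alone). The YAP and TEAD list was lower (camera adjusted p = 0.0402; adjusted p = 0.527 with an estimated correlation). AMOTL2 (-1.65) and the kinase NUAK2 (-1.28) fell, and the receptor AXL (0.79) and CYR61 (0.51) rose. Of 20 TGF-beta and mesenchymal transition genes, 5 rose, 6 fell and 9 did not pass (5 up and 7 down adjusted over the list alone). The TGF-beta list did not pass (camera adjusted p = 0.141; adjusted p = 0.446 with an estimated correlation). SNAI1 (0.74) rose, and the cadherin CDH2 (-1.21) and SKIL (-1.001) fell. Of 15 NF-kB targets and inflammatory mediators, 2 rose, 7 fell and 6 did not pass (4 up and 7 down adjusted over the list alone). The NF-kB list did not pass (camera adjusted p = 0.157; adjusted p = 0.527 with an estimated correlation). TNFAIP2 (2.21) and the cytokine LIF (1.37) rose, and the NF-kB inhibitor TNFAIP3 (-0.88) and NFKB1 (-0.77) fell. Of 26 interferon-stimulated genes, 4 rose, 3 fell and 19 did not pass (4 up and 3 down adjusted over the list alone). The interferon list did not pass (camera adjusted p = 0.913; adjusted p = 0.915 with an estimated correlation). OAS2 (2.52) and IFI27 (1.29) rose, and IFIT1 (-1.29) and IFITM1 (-0.57) fell. OAS2 had 15 and 3 reads in DMSO replicates 1 and 2, and its change was 3.51 without DMSO replicate 1 and 1.54 without DMSO replicate 2 (adjusted p = 0.0235 and 0.0613). Of 22 immediate early and feedback genes of the MAPK pathway, 6 rose, 5 fell and 11 did not pass (6 up and 5 down adjusted over the list alone). The immediate early list did not pass (camera adjusted p = 0.676; adjusted p = 0.915 with an estimated correlation). FOSB (1.82) and FOS (1.40) rose, and the phosphatase DUSP4 (-0.91) and ETV4 (-0.80) fell. The immediate early median was -0.18 (log2) in DMSO replicate 1 relative to DMSO replicate 2. Median and mean differed in sign for the TGF-beta list (a median log2 change of -0.13 and a mean of 0.11), the NF-kB list (median log2 change of -0.21 and a mean of 0.06) and the interferon list (median log2 change of -0.04 and a mean of 0.04). The beta-catenin call ended without AMF replicates 1 or 2 or DMSO replicate 2 (adjusted p = 0.0676, 0.074 and 0.0562) and the YAP call on leaving out AMF replicate 1, AMF replicate 2, DMSO replicate 1 or DMSO replicate 2 (0.209, 0.304, 0.0763 and 0.139).

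Ribosomal protein genes were slightly lower and mitochondrially encoded genes higher in AMF. Of 47 cytosolic ribosomal protein genes, 2 rose, 15 fell and 30 did not pass (2 up and 16 down adjusted over the list alone). The ribosomal protein list was lower (camera adjusted p = 0.00225; adjusted p = 0.446 with an estimated correlation), with values from -0.31 for RPL5 and -0.19 for RPL37 to 0.16 for RPL24 and 0.18 for RPS18. Of 26 genes of ribosome biogenesis, 12 rose, 3 fell and 11 did not pass (12 up and 3 down adjusted over the list alone). The ribosome biogenesis list was higher (camera adjusted p = 0.0402; adjusted p = 0.446 with an estimated correlation). RRP12 (0.49) and MYC (0.45) rose, and UBTF (-0.29) and NOP58 (-0.22) fell. Of 15 mitochondrially encoded genes, 6 rose, 1 fell and 8 did not pass (6 up and 1 down adjusted over the list alone). The mitochondrial list was higher (camera adjusted p = 0.0307; adjusted p = 0.575 with an estimated correlation). The oxidase subunit MT-CO1 rose from 405655 ± 6882 in DMSO to 582960 ± 4964 in AMF (0.52, SE 0.0301) and MT-CO2 by 0.43, and the small ribosomal RNA MT-RNR1 fell (-0.33). Of 32 nuclear genes of oxidative phosphorylation, 9 rose, 2 fell and 21 did not pass (9 up and 2 down adjusted over the list alone). The oxidative phosphorylation list did not pass (camera adjusted p = 0.119; adjusted p = 0.609 with an estimated correlation). NDUFV2 (1.005) and NDUFB3 (0.59) rose, and NDUFS3 (-0.22) and UQCRC1 (-0.12) fell. Of 19 actin and SRF target genes, 11 rose, 3 fell and 5 did not pass (11 up and 4 down adjusted over the list alone). The actin list was higher (camera adjusted p = 0.0117; adjusted p = 0.527 with an estimated correlation). TAGLN (1.09) and the myosin light chain MYL9 (0.81) rose, and SRF (-0.25) and ACTG1 (-0.14) fell. Of 14 tubulin genes, 5 rose, 2 fell and 7 did not pass (5 up and 2 down adjusted over the list alone). The tubulin list did not pass (camera adjusted p = 0.537; adjusted p = 0.806 with an estimated correlation). TUBB4A (1.77) and TUBB6 (1.03) rose, and the tubulin-binding STMN1 (-1.01) and TUBB (-0.19) fell. Of 17 replication-dependent histone genes, whose RNA mostly lacks the poly(A) tail that was selected, 2 rose, 2 fell and 13 did not pass (2 up and 2 down adjusted over the list alone). The histone list did not pass (camera adjusted p = 0.913; adjusted p = 0.915 with an estimated correlation). HIST1H1C (0.78) and HIST1H2BK (0.77) rose, and HIST2H2AC (-1.21) and HIST1H1E (-1.01) fell. Of 17 host genes of small nucleolar RNAs and other long non-coding RNAs, 5 rose, 6 fell and 6 did not pass (5 up and 6 down adjusted over the list alone). The non-coding RNA list did not pass (camera adjusted p = 0.846; adjusted p = 0.915 with an estimated correlation). LUCAT1 (0.67) and NEAT1 (0.54) rose, and the imprinted H19 (-1.29) and SNHG7 (-0.72) fell. The median and mean of that list differed in sign, with a median log2 change of -0.01 and a mean of 0.09. The ribosome biogenesis call ended on leaving out AMF replicate 1, AMF replicate 2, DMSO replicate 1 or DMSO replicate 2 (adjusted p = 0.209, 0.184, 0.105 and 0.0601), the mitochondrial and actin calls without AMF replicates 1 or 2 or DMSO replicate 2 (0.39, 0.477 and 0.123 and 0.101, 0.124 and 0.0806), and the oxidative phosphorylation list passed without DMSO replicate 1 (0.0327). The ribosomal protein call ended among genes with a mean of at least 100 (adjusted p = 0.108) and with the replicate number as a block (0.0676).

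Lists of markers of other cell types did not pass with camera, whereas fry called the fibroblast list lower (adjusted p = 0.0197) and the blood cell list higher (adjusted p = 0.0428). Of 5 tested fibroblast and stellate cell markers, 0 rose, 3 fell and 2 did not pass. The fibroblast list did not pass (camera adjusted p = 0.0628; adjusted p = 0.446 with an estimated correlation), with COL1A1 at 101 ± 21.0 in DMSO and 6.91 ± 1.89 in AMF (-3.70) and PDGFRB at 101 ± 9.78 in DMSO and 19.7 ± 8.92 in AMF (-2.37). With library totals as scaling that list was lower in AMF (adjusted p = 0.0487). Of 7 leukocyte and red cell markers, 2 rose, 2 fell and 3 did not pass. The blood cell list did not pass (camera adjusted p = 0.932; adjusted p = 0.947 with an estimated correlation). CD14 rose (1.53) and LYZ, at 24899 ± 433 in DMSO and 17916 ± 669 in AMF, fell (-0.48). The test of that list pointed down against a median log2 change of 1.53 and a mean of 0.91. Among 4 endothelial markers, too few for the list test, 2 rose, 0 fell and 2 did not pass, with rises in PECAM1 (0.79) and VWF (2.04). VWF had 8 and 1 reads in DMSO and 26 and 11 in AMF, and its change was 3.12 without DMSO replicate 1 and 0.97 without DMSO replicate 2 (adjusted p = 0.0757 and 0.374). Of 7 markers of other epithelial lines, 2 rose, 1 fell and 4 did not pass. The epithelial list did not pass (camera adjusted p = 0.61; adjusted p = 0.716 with an estimated correlation), with a median log2 change of -0.33 and a mean of 0.64. The intestinal genes CDX2, with 3 reads over the DMSO libraries and 235 over the AMF libraries (ratio 75.5, 95% exact interval 25.5 to 369), and KRT20 (21.2 ± 3.90 in DMSO and 136 ± 3.14 in AMF) rose, and the microvillus gene VIL1 fell (-0.19). Adjusted over each list alone the numbers up and down were the same in these 4 lists.

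**Figure D3:**
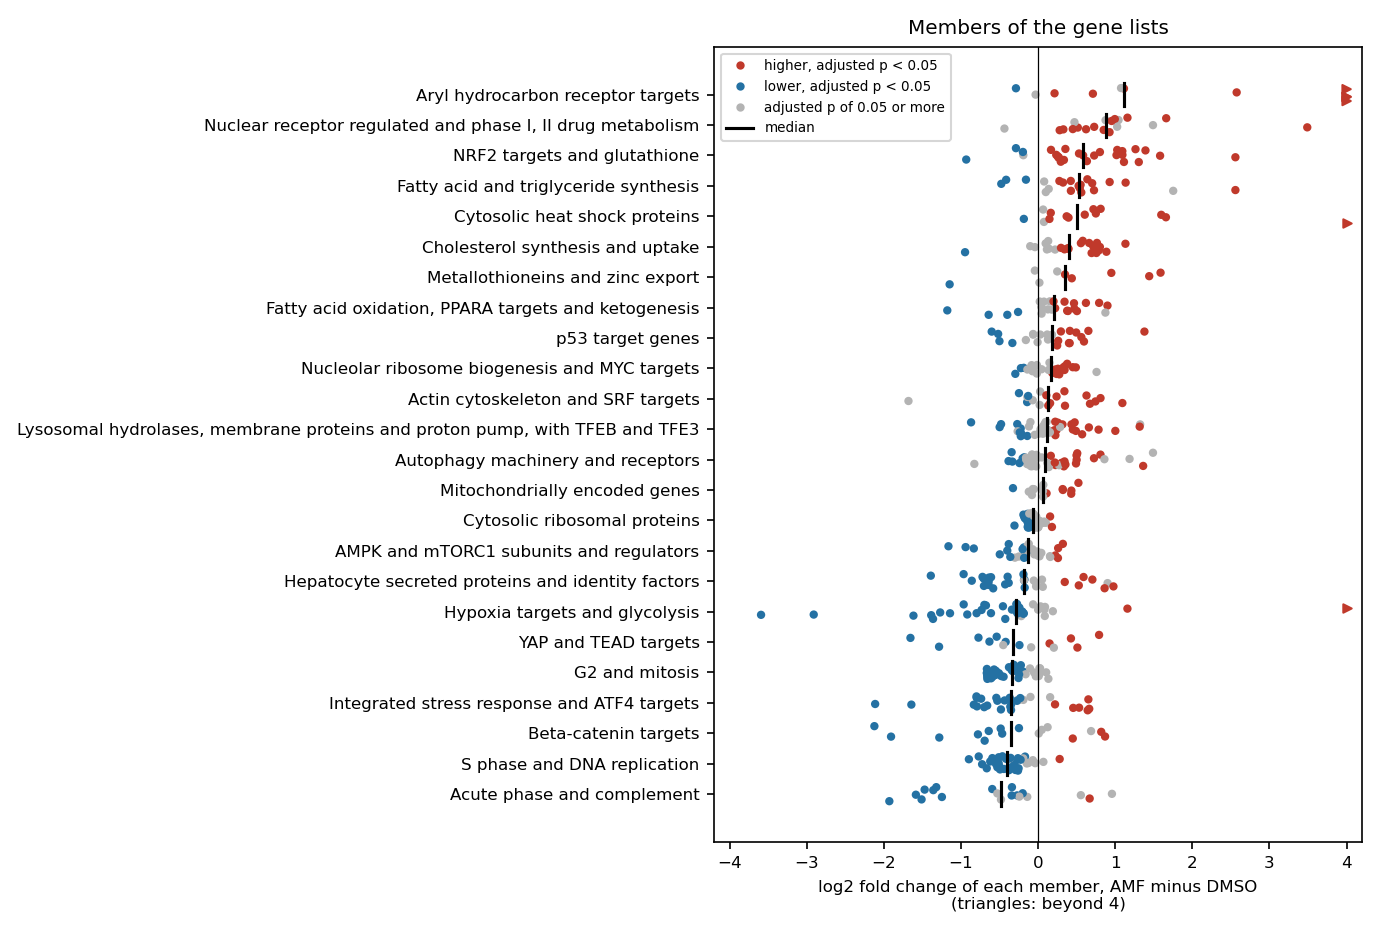
Log2 change of AMF against DMSO (horizontal axis) for each tested member of the 23 lists that passed camera with the preset correlation and of the autophagy list, in order of the list median (black bar). Red and blue points passed an adjusted p of 0.05 upwards and downwards, grey points did not, and triangles lie beyond 4. The aryl hydrocarbon receptor list has the highest median (1.11) and the acute phase list the lowest (-0.48).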

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

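Added after seeing the data were the fits on deposited log2 values, with voom, with library totals, with a mean of at least 10 and the list tests without single libraries. Of the 166 named genes, none changed direction under the settings run. For the fits without 1 library this was fixed beforehand, since both AMF libraries lay on the same side of both DMSO libraries in each gene. The main count of 7578 genes (3718 up, 3860 down) moved by less than 1.5 times with a pseudocount of 0.1 (6750), no filter (6580), named genes alone (7266), an adjusted p under 0.01 (5469), deposited values (7562), voom (7714), library totals (7628) and a mean of at least 10 (7752). With a log2 change of at least 1 it was 1672 (1183 up, 489 down). Leaving out 1 library gave 0 to 3531 genes with limma-trend (0 to 1753 up, 0 to 1780 down) and 1315 to 6776 with voom (636 to 3043 up, 679 to 3733 down). These fits keep 1 degree of freedom between samples and assume that the lone library varies like the other group, and without AMF replicate 1 or 2 the prior degrees of freedom of limma-trend fell from 11.9 to 0.995 and 1. With the replicate number as a block 8157 genes passed (4049 up, 4108 down) and 21 lists. Same-numbered libraries did not deviate together (correlation 0.014 over 15845 genes, 2 pairs), so the numbers are not taken to pair the samples.

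Of 41 lists, 23 passed (13 up, 10 down). With an estimated correlation 0 passed (0 up, 0 down). The estimate lay under the preset 0.01 for the NRF2 (0.002), lysosomal (0.004) and ribosomal protein (-0.019) lists, among others. A higher correlation between genes therefore does not account for the end of those calls. With 4 libraries in 2 groups, camera has few residual degrees of freedom for that setting, and its lowest adjusted p was 0.446. The 0 calls there therefore say little of single lists. Other lists had high estimates, such as cholesterol (0.879) and heat shock (0.801). How far these add to the end of their calls was not tested. Ranks kept 16 (8 up, 8 down), genes with a mean of at least 100 left 16 of 37 (10 up, 6 down), fry called 22 and library totals 26. Without a single library 13 to 23 lists passed (6 to 14 up, 7 to 9 down). Fry did not call the cholesterol, integrated stress, hypoxia, hepatocyte, metallothionein and YAP lists, and called the autophagy, amino acid and blood cell lists up and the TGF-beta and fibroblast lists down. Ranks ended the actin, metallothionein, mitochondrial, p53, ribosome biogenesis, beta-catenin and YAP calls. A mean of at least 100 ended the AMPK and mTORC1, metallothionein, mitochondrial, ribosomal protein, ribosome biogenesis, beta-catenin and YAP calls, and the block the AMPK and mTORC1, ribosomal protein and ribosome biogenesis calls. Planned count models (with size factors or trimmed means, and a CPM filter) were not run, since the test was set by the deposited unit, which is log2, and the recovered reads were tested with voom alone. Tests for a table of comparisons did not apply. Depth limits genes with few reads, such as LIM2 and CA12, whose DMSO level rests on 1 read.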

Other observations

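The genes and tests below were chosen after seeing the data, except the hypoxia and cholesterol lists and their camera and fry tests, which were planned, and the germline list test, whose bounds were set before its result was seen. A set of 45 genes had a mean under 2 normalized counts in DMSO and over 20 in AMF, against 1 gene, the microRNA gene MIR483, with the reverse. GSTP1, a glutathione transferase, had 0 reads in both DMSO libraries and 176 ± 0.465 normalized counts (SD, n = 2) in AMF, at least 115.7-fold higher against 3 reads over the group. The keratin KRT79 (59.9 ± 8.54), the calcium channel subunit CACNA1A (48.3 ± 13.2) and the proteoglycan SPOCK1 (34.9 ± 6.01) likewise went from 0 reads. The phospholipase PLA2G4F (197 ± 10.3) and the melanosome transport gene MLPH (157 ± 24.0) each had 1 read over the DMSO libraries. AHRR, the repressor of the aryl hydrocarbon receptor, had 2 reads in DMSO and 46.3 ± 1.44 normalized counts in AMF.

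Among 7 genes that write, maintain or remove DNA methylation, 6 fell in AMF (limma, at an adjusted p under 0.05) and DNMT3B did not pass (0.17, adjusted p = 0.0848). The log2 changes were -0.91 for TET1, -0.73 for UHRF1, -0.63 for DNMT3A, -0.55 for TET2, -0.53 for TET3 and -0.33 for DNMT1. UHRF1, which brings DNMT1 to newly copied DNA, had 4751 ± 318 in DMSO and 2869.8 ± 47.8 in AMF. Genes of S phase and DNA replication fell too (32 of 40, median log2 change -0.40). The falls are therefore not shown to be particular to genes of DNA methylation.

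Genes with few reads were higher in AMF. The median log2 change was 0.51 over 2169 coding genes with a mean of 1 to 10 normalized counts. It was 0.29 over all 7983 genes of that level, coding or not, and -0.04 over 5098 coding genes with a mean of 1000 or more. In both DMSO libraries 4238 genes had 0 reads, against 2122 in both AMF libraries. The tables argue against depth, since after thinning to the smallest library the lower AMF library still detected 1588 genes more than the higher DMSO library. Scaling by 1 factor per library shifts genes of every level nearly alike. With library totals as scaling the coding medians were 0.52 (mean of 1 to 10) and -0.02 (mean of 1000 or more), and the counts of genes with 0 reads use no scaling. Those totals are nearly proportional to the size factors, so these medians could hardly differ from the main fit and test nothing. A single factor per library could hardly open a gap between levels, whatever its value. A shift of all levels together was not tested. Genomic DNA in the AMF libraries cannot be told apart from higher transcript levels: 50 coding olfactory and taste receptor genes, which liver cells hardly transcribe, had an AMF to DMSO read ratio of 1.14 (95% bootstrap interval over genes 0.852 to 1.687) against 1.52 for the other coding genes under 10, although with pseudogenes and unmatched names (95 genes) it was 0.966 (0.798 to 1.35), and the rule that an interval holding 1 decides nothing was set after these values were seen. Loss of DNA methylation at silenced genes is a hypothesis that also stays open. The median change of 19 germline genes was 0.91 against 0.38 for matched random lists. It lay at percentile 94.99 of 10000, just under the bound of 95. Of the 19, 3 rose and 0 fell, against 3718 up and 3860 down among all 23828 genes tested. Not all of the 19 were silent in DMSO. TEX19, which rose, had 635 ± 116 normalized counts there. PIWIL2 (47.6 ± 3.76 in DMSO) and SYCP3 (28.9 ± 2.69 in DMSO) did not pass. A wider release of transcription by AMF may account for the rise of genes with few reads as well and was not tested.

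Hypoxia targets and glycolytic genes were lower in AMF with camera (adjusted p = 9.59e-10; adjusted p = 0.446 with an estimated correlation), fry did not call them (adjusted p = 0.0514), and the list also differed between the DMSO libraries. Its median log2 change was -0.258 against DMSO replicate 2 alone, where the list was lower. The cholesterol list, also higher in DMSO replicate 1 than in DMSO replicate 2, moved the opposite way in AMF (median 0.40 against -0.28). A culture state that moves both lists alike therefore does not give both changes by itself. The values do not exclude such a state for the hypoxia list alone, since AMF cultures may lie further along it than DMSO replicate 2. The bounds of this comparison were set after the values were seen. With library totals as scaling the hypoxia median was -0.26, against -0.28 in the main fit. Those totals are nearly proportional to the size factors, so a larger change of scale was not tested. A difference in cell density or oxygen use between AMF and DMSO cultures, or an action of AMF on these genes, may account for the pattern, and neither was tested.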
